A study of Mus musculus with 2 samples.

How the data were processed

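Nuclei from the amygdala of mice aged 6 to 8 weeks were profiled by droplet single-nucleus RNA sequencing with version 2 of the 10x 5' gene expression kit, which counts tags near the 5' end of transcripts. There were 2 samples, 1 library per genotype, labelled wild type (WT) and Sema6d-/- (KO), both with the strain given as C57BL6/J. How many animals went into a library, their sex and the part of Sema6d that is deleted are not given in the sources used here. The deposited matrices hold raw UMI counts, with 32285 Ensembl gene identifiers against nucleus barcodes, and no value in them was negative or fractional. Per the labels, the authors made them with Cell Ranger 6.0.0 against the mm10 build. The annotation version, the handling of intronic reads and the settings for calling nuclei are not given. Symbols were assigned by identifier for 32158 genes, and 127 kept the identifier alone. Gene positions are those of the GENCODE annotation of the same build.

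The deposited WT library held 11060 barcodes with 85124128 UMIs, and the KO library 8666 barcodes with 60402979 UMIs. Barcodes with fewer than 500 genes (12 in WT, 143 in KO) or more than 5% mitochondrially encoded UMIs (259 and 428) were left out. Scrublet, as implemented in scanpy 1.11.5, was run on each library with an expected rate of 0.8% per 1000 nuclei, and the called doublets were removed (459 in WT, 277 in KO). This left 10332 WT nuclei with 78726439 UMIs and 7856 KO nuclei with 55885826 UMIs. Counts were scaled to 10000 UMIs per nucleus and log-transformed, and 2000 variable genes were chosen with the library as batch key. Clusters came from 30 principal components, 15 exact nearest neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), with no integration of the libraries.

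Clusters were named from 15 lists of cell type markers and described with 13 lists of neuron subtype markers. A name needed at least 20 nuclei, a score of at least 0.35, a lead of 0.1 over the next class and at least 3 markers detected in 10% of nuclei. The 10 leading genes of a cluster also had to hold no more markers of another class than of its own. The scoring and its fold reference were set, and once changed, after the clusters had been seen. Clusters 2, 6 and 31 scored as inhibitory neurons but were kept out of that class because 1 of their leading genes, Gli3 or Sox6, also stood on a glial list. Clusters 2 and 6 were therefore compared by number.

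With 1 library per genotype no difference was tested, and no p-value or standard error was computed from nuclei. UMIs were summed over the nuclei of a class in each library and expressed per 1e+06 UMIs of the class (CPM). Ratios are log2 of CPM in KO over CPM in WT. Intervals are exact 95% Poisson or binomial (Clopper-Pearson) intervals. They cover counting error only, not differences between animals, dissections or library preparations. A count of 0 was set to a floor of 3 counts. For 24 gene lists fixed before the data were examined, the median ratio was taken over members with at least 20 UMIs in the class. Its percentile was read among 10000 random lists of the same size, matched on expression in 20 bins. The percentile describes these libraries and is not a test of genotype. Alternatives were computed for 61 such medians. Medians given beside them for markers of other cell types in glia have none.

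Genes were named by a rule of size fixed before the data were examined. In a class with at least 100 nuclei in each library, a gene needed 100 UMIs over both libraries, 20 CPM in the higher library and a class CPM of at least 25% of its highest class. It also needed the same direction in at least 2 of every 3 clusters that held 20 nuclei of each library. Oligodendrocyte precursors, microglia and clusters 2 and 6 are 1 cluster each, so there this rule is met by construction. Astrocytes and oligodendrocytes have 2 clusters each. Mitochondrially encoded genes, Y-linked genes, Xist and unnamed gene models were left out. The 10 highest and 10 lowest ratios were named in excitatory and in inhibitory neurons, and the 4 highest and 4 lowest in each other class. Sema6d, Plxna1, Plxna4 and up to 4 members of each list were named as well. Some genes that these rules chose are not reported here and were left out of the alternatives for named genes. Other genes that are named were chosen after their values were seen, and this is said beside them. The share of nuclei with a Sema6d UMI was taken after thinning each nucleus to 1000 UMIs, which left out 103 WT and 182 KO nuclei.

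The alternatives fixed in advance were a minimum of 200 or 1000 genes per nucleus, doublets kept, resolutions 0.5 and 2.0, 50 components, and WT clustered alone with KO nuclei assigned to it. For ratios they were median-of-ratios and TMM scaling (edgeR 4.0.16 in R 4.3.3), a minimum of 1 or 100 UMIs, the same cluster weights in both libraries, doublets kept and thinned nuclei. Alternatives without clusters 1, 36, 17 and 19 or without border macrophage nuclei were added after seeing the data. The ratio and list calculations were tested on simulated class totals in which 200 genes had known folds. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, with figures from matplotlib 3.10.9.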

Results

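Single-nucleus transcriptomes were collected from the amygdala of mice aged 6 to 8 weeks, in 1 library labelled WT and 1 labelled Sema6d-/- (KO). Sema6d is a transmembrane semaphorin, a guidance molecule that binds plexins. The series sets out to describe gene expression in single cells of the amygdala in both genotypes. After filtering, the WT library held 10332 nuclei with 78726439 UMIs, a median of 7178 UMIs and 2995.5 genes per nucleus. The KO library held 7856 nuclei with 55885826 UMIs, a median of 6389 UMIs and 2846 genes. With 1 library per genotype, every difference below is between these libraries and was not tested. Each interval in brackets is an exact 95% interval for counting error only.

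The first comparison asks how much Sema6d RNA each class of nuclei held. Oligodendrocyte precursors had the highest level in both libraries, with 1410 CPM in WT and 1492 CPM in KO. Inhibitory neurons held 853 CPM in WT (843 to 863) and 834 CPM in KO (823 to 846), and excitatory neurons 585 CPM (573 to 596) and 709 CPM (695 to 723). Astrocytes held 624 and 641 CPM, oligodendrocytes 323 and 340 CPM, and microglia 87.5 and 79.5 CPM, the last from 16 and 32 UMIs. Over all nuclei the level was 632 CPM in WT and 686 CPM in KO. After thinning to 1000 UMIs, 36.5% of excitatory nuclei in WT (34.2 to 38.9) and 43.0% in KO (40.1 to 45.9) had a Sema6d UMI. In microglia, a type with little Sema6d, that share was 6.06% in WT and 3.95% in KO.

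Sema6d RNA was thus not lower in the library labelled KO in excitatory neurons or over all nuclei, and in inhibitory neurons the ratio of -0.03 turned to 0.02 with a minimum of 1000 genes per nucleus. The gene (ENSMUSG00000027200) spans 578 kb on chromosome 2, from 124089969 to 124667770 in mm10. Since the deleted part is not given, and tags from the 5' end and from unspliced nuclear RNA can be counted without a protein being made, these counts neither support nor question the label. The names KO and WT below are those of the labels.

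**Figure D1:**
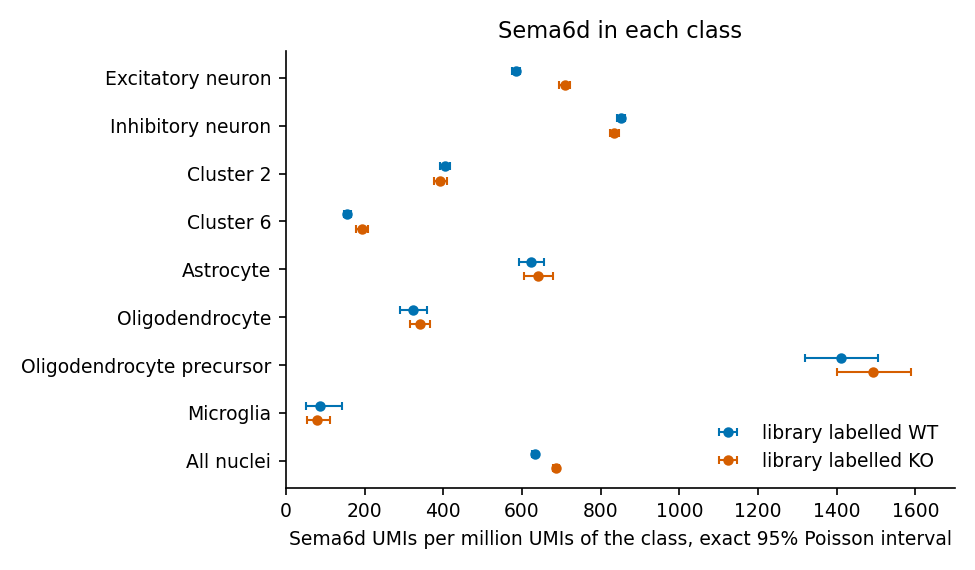
Sema6d CPM of each class in the 2 libraries, with exact 95% Poisson intervals for counting error. Over all nuclei the level is 632 CPM in the library labelled WT and 686 CPM in the library labelled KO.

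Among partners of the class 6 semaphorins, Plxna4, a plexin receptor, was lower in the KO library in excitatory neurons, at 610 CPM in WT and 553 CPM in KO (log2 ratio -0.14, -0.18 to -0.10). In inhibitory neurons it stood at 472 and 421 CPM (log2 ratio -0.16, -0.20 to -0.13), and it was lower in 8 of 8 excitatory and 12 of 12 inhibitory clusters compared. Both ratios lie within the spread of other genes. For genes with at least 200 UMIs the 5th to 95th percentile ran from -0.43 to 0.48 in excitatory and from -0.38 to 0.44 in inhibitory neurons. Plxna1, another plexin, was near 20 CPM, with 25.5 CPM in WT and 21.7 CPM in KO in excitatory neurons and 22.4 and 23.4 CPM in inhibitory neurons. The list of semaphorins, plexins and neuropilins had a median ratio of -0.10 in excitatory neurons, with 10 of 29 members higher and 19 lower (percentile 2.19). In inhibitory neurons the median was 0.05, or 0.18 with doublets kept, with 18 members higher and 11 lower (percentile 75.8). Sema5b was lower in both, at -0.65 and -0.46, while Sema3c stood at 2.37 in excitatory neurons, where it is a leading gene of cluster 36, which is mostly of the KO library, and at 0.14 with the same cluster weights.

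The next comparison asks which classes made up each library. Oligodendrocytes, the myelin-forming cells, were 4.94% of nuclei in WT (4.53 to 5.37) and 14.0% in KO (13.2 to 14.8), a ratio of 2.83. Microglia, the resident macrophages, were 1.02% in WT (0.832 to 1.23) and 2.95% in KO (2.59 to 3.35), a ratio of 2.91. Oligodendrocyte precursors were 1.60% and 2.60%, and fibroblasts 0.184% and 1.64%, the last from 19 and 129 nuclei. Astrocytes took 8.81% of nuclei in WT and 8.53% in KO, mural cells 0.648% and 0.547%, and endothelial cells 0.242% and 0.280%, each with overlapping intervals. All neuron clusters together were 79.1% of nuclei in WT (78.3 to 79.9) and 63.8% in KO (62.7 to 64.9).

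Inhibitory neurons were 41.2% of nuclei in WT and 36.6% in KO, a difference of -4.56 points that moved to -9.24 with doublets kept and -8.86 at resolution 0.5. With clusters 2, 6 and 31, which scored as inhibitory, they were 62.5% and 49.0%. Excitatory neurons were 15.7% and 14.3%, a difference that turned to 0.739 points in favour of KO with a minimum of 1000 genes per nucleus. There were 0.382 excitatory nuclei per inhibitory nucleus in WT (0.361 to 0.405) and 0.391 in KO (0.364 to 0.419). With clusters 2, 6 and 31 in the denominator these were 0.252 (0.238 to 0.266) and 0.292 (0.273 to 0.312). The ratio without these clusters moved with the settings, and ranged from 0.260 to 0.531 in WT and from 0.278 to 0.608 in KO.

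**Figure D2:**
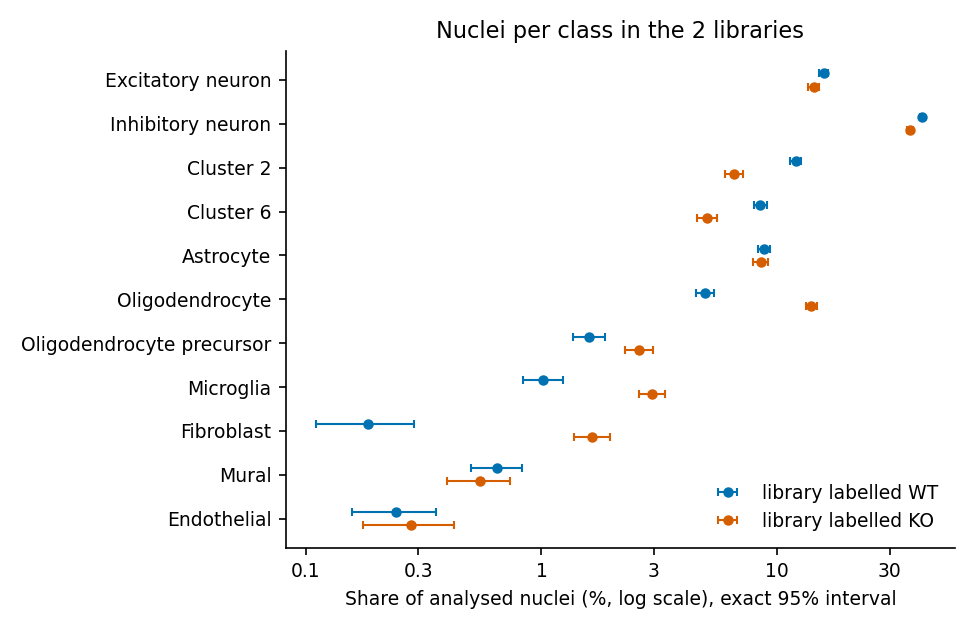
Share of analysed nuclei in each class (percent, log scale) in the 2 libraries, with exact 95% binomial intervals for counting error. Oligodendrocytes are 4.94% of the library labelled WT and 14.0% of the library labelled KO, while astrocytes are 8.81% and 8.53%.

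Within neurons, the comparison asks how each cluster's share differed. There were 8176 neurons in WT and 5014 in KO, in 25 clusters. Cluster 2, which carries Ebf1 and Rgs9 and scored highest for D1 medium spiny neurons, was 15.2% of neurons in WT and 10.3% in KO (ratio 0.679, 0.612 to 0.753). Cluster 6, with Drd2 and Rgs9 and a D2 medium spiny profile, was 10.7% and 7.88% (ratio 0.736, 0.652 to 0.830). Of the other clusters that scored highest for these types, cluster 11 had a ratio of 0.676 (0.554 to 0.821) and cluster 7 of 1.0 (0.867 to 1.15) on the D2 list, and cluster 15 of 0.795 (0.633 to 0.994) and cluster 27 of 1.89 (1.42 to 2.50) on the D1 list. Cluster 8, with Nxph1, Sox6 and Moxd1, was 3.51% and 6.18% (ratio 1.76, 1.5 to 2.08), and cluster 1, with Prlr, Htr7 and Foxp2, was 13.9% and 17.9% (ratio 1.29). Cluster 36, with Sim1, a transcription factor of the hypothalamus and medial amygdala, held 14 WT and 75 KO nuclei, 0.171% and 1.5% of neurons (ratio 8.74, 4.90 to 16.7). It scored highest for basolateral amygdala neurons (0.481), although Sim1 stands on the list of medial amygdala and hypothalamic neurons. Cluster 29, with Tcf7l2 and Slc17a6 and the highest score for thalamic neurons, had a ratio of 1.54 (1.14 to 2.08). Cluster 28, with Nr4a2 and Ntng2 as in claustrum and endopiriform neurons, had a ratio of 0.702 (0.508 to 0.960). Several of these markers belong to striatum, claustrum, thalamus or hypothalamus.

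In neurons, the gene lists ask which functions differed in level. Activity-induced genes, which neurons transcribe within minutes of stimulation, were lower in the KO library in most cases. In excitatory neurons 25 of 25 members were lower, with a median log2 ratio of -1.01 (percentile 0 among random lists), and in inhibitory neurons 22 of 25 with a median of -0.80 (percentile 0). Arc, which regulates AMPA receptor traffic at synapses, stood at 41.4 CPM in WT and 13.6 CPM in KO in excitatory neurons (log2 ratio -1.61, -1.85 to -1.38) and at 30.3 and 10.6 CPM in inhibitory neurons (-1.51, -1.71 to -1.31). Homer1, a postsynaptic scaffold with an activity-induced short form, stood at 482 and 310 CPM in excitatory neurons (-0.64) and 325 and 224 CPM in inhibitory neurons (-0.54). The transcription factor Npas4 stood at -1.59 and -1.63 in the excitatory and inhibitory class, and Egr1 at -1.39 and -1.07, both chosen after their values were seen. Nr4a2 in excitatory neurons stood at -0.19, which turned to 0.17 with the same cluster weights in both libraries. In clusters 2 and 6 the list median was -0.75 and -0.62, the latter -0.38 over genes with at least 100 UMIs, and in astrocytes, where Homer1 stood at -0.53 and Nptx2 at 0.92, it was -0.07 (percentile 38.1). The median mitochondrial percentage of the neurons was lower in KO as well, at 0.570 in WT and 0.187 in KO in excitatory and 0.711 and 0.318 in inhibitory neurons.

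**Figure D3:**
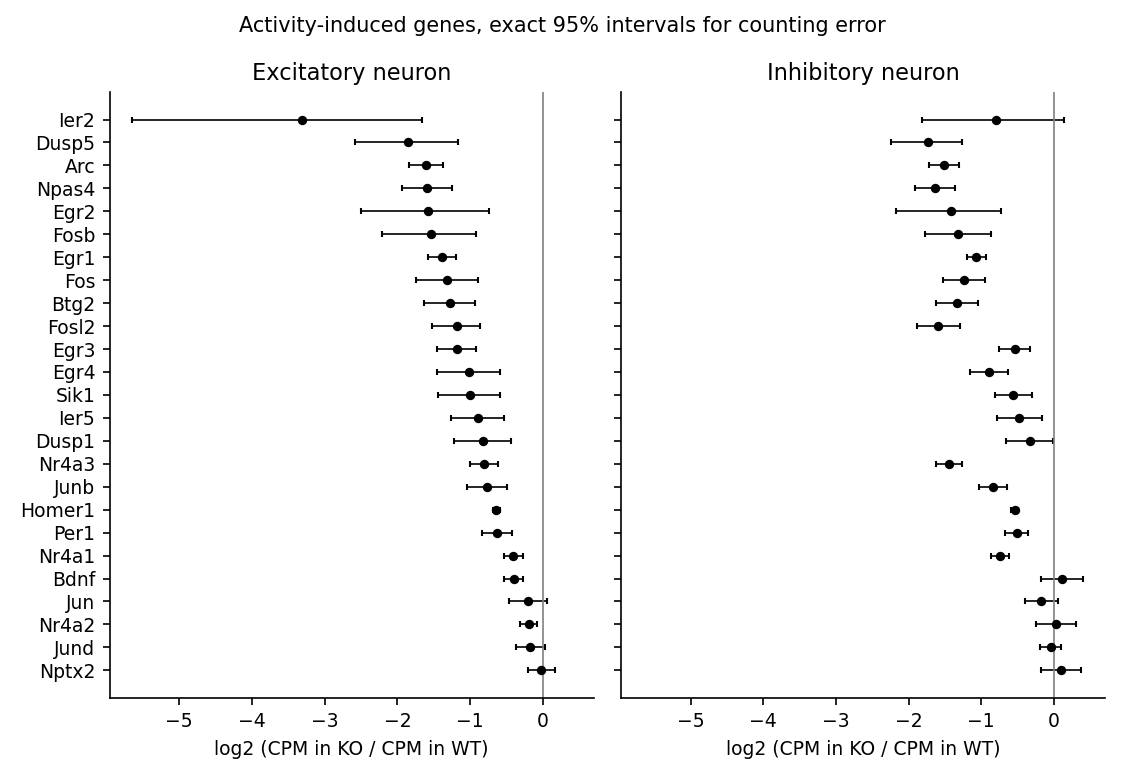
Log2 ratio of CPM in the library labelled KO over CPM in the library labelled WT for the 25 activity-induced genes in excitatory and inhibitory neurons, with exact 95% intervals for counting error. All 25 lie below 0 in excitatory neurons and 22 in inhibitory neurons; the direction of Nr4a2 in excitatory neurons flips with the same cluster weights.

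Scaffolds and kinases of the postsynaptic density were also lower in the KO library, with 15 of 20 members lower in excitatory neurons (median -0.20, percentile 0.01) and 17 of 20 in inhibitory neurons (median -0.22, percentile 0.01). Homer1 is a member of this list too. Dlgap3, a scaffold of striatal synapses, stood at 131 CPM in WT and 88.1 CPM in KO in inhibitory neurons (-0.57). Dlgap1 differed little, at 0.01 and 0.07, and Dlg2, the most abundant member, at -0.05 in inhibitory neurons. In clusters 2 and 6 the medians were -0.16 and -0.19, and the list was also lower in astrocytes (-0.18), microglia (-0.25) and oligodendrocytes (-0.35), so this was not particular to neurons. Genes of the stress hormone response were lower as well, with medians of -0.22 in excitatory neurons (10 of 13 lower), -0.21 in inhibitory neurons (11 of 13 lower), -0.25 in cluster 2 and -0.48 in cluster 6, the last at 0.000346 in thinned nuclei. Cdkn1a, a cell cycle inhibitor, stood at -1.34 and -1.11 in the neuron classes, and Fkbp5, a glucocorticoid-induced chaperone, at 0.15 in inhibitory neurons. Per1 is on both the stress hormone and the activity-induced list. The place of the stress hormone medians among random lists is not given here.

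Neuropeptides and their granule proteins were higher in the KO library, with 18 of 20 members higher in inhibitory neurons (median 0.39, percentile 100) and 14 of 19 in excitatory neurons (median 0.19, percentile 98.2). The list was at 0.19 in oligodendrocytes too, and lists of other cell types were also higher in inhibitory neurons, with medians of 0.58 for myelin genes, 0.41 for homeostatic microglia and 0.31 for the free RNA list. Penk, the enkephalin precursor, stood at 533 CPM in WT and 578 CPM in KO in inhibitory neurons (0.12) and at 1187 and 2276 CPM in cluster 6 (0.94). In cluster 2, Tac1, the substance P precursor, stood at 155 and 228 CPM (0.55). The list medians there were 0.22 in cluster 2, or 0.52 in thinned nuclei, and 0.38 in cluster 6. Adcyap1, the precursor of PACAP, stood at 1.06 in excitatory neurons, and Crh, corticotropin-releasing hormone, at -0.42 in inhibitory neurons (-0.74 to -0.11). Nxph1 stood at 0.06 in excitatory and 0.26 in inhibitory neurons, which turned to -0.11 and -0.03 with the same cluster weights.

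Synaptic adhesion molecules were higher in inhibitory neurons, with 30 of 39 members higher (median 0.11, percentile 100), and had a median of 0.03 in excitatory neurons (percentile 91.0). Lrrtm1 stood at 0.40 and Tenm4 at -0.21 in inhibitory neurons. The GABAergic synapse had medians of 0.07 in both classes, with 17 of 28 members higher in each (percentiles 95.4 and 97.4). Slc32a1, the vesicular GABA transporter, stood at 73.2 CPM in WT and 101 CPM in KO in inhibitory neurons (0.46, 0.38 to 0.55), and Gabrg3, a GABA receptor subunit, at -0.16. Glutamate receptors had medians near 0, at -0.00 and -0.05, although Grm4, a presynaptic metabotropic receptor, stood at -0.88 and -0.70. Excitatory and inhibitory medians were -0.07 and 0.01 for presynaptic release, -0.08 and 0.08 for ephrin, Slit and netrin guidance (the latter -0.0112 with the same cluster weights), -0.02 and 0.04 for monoamine and opioid receptors, and -0.02 and -0.05 for potassium channels. They were -0.08 and -0.09 for sodium and calcium channels and 0.10 and 0.07 for oxidative phosphorylation. Cacna1c, an L-type calcium channel, stood at -0.31 and -0.35. Heat shock genes had medians of -0.18 and -0.16, which turned to 0.03 and 0.01 in thinned nuclei, so their direction is not settled. The medians in thinned nuclei can rest on fewer members, so such a shift is not one of depth alone.

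Transcripts of other cell types, which can reach droplets as free RNA, also differed. The share of free RNA in the droplets was not measured. Myelin genes had medians of 0.74 in excitatory and 0.58 in inhibitory neurons, and 0.16 and 0.77 in thinned nuclei. Ptgds, a prostaglandin synthase of meninges and oligodendrocytes, stood at 21.6 CPM in WT and 91.0 CPM in KO in excitatory neurons (2.07) and at 29.0 and 129 CPM in inhibitory neurons (2.15). Mbp went the other way, at -0.55 and -0.56. The free RNA list as a whole had medians of -0.04 in excitatory neurons, 0.31 in inhibitory neurons, 0.45 in astrocytes, 0.24 in oligodendrocytes, -0.04 in precursors and 0.50 in microglia. In thinned nuclei it was 0.07 in inhibitory neurons, 0.14 in astrocytes and 0.26 in precursors. The list of Y-linked genes and Xist had medians of 0.21 in excitatory and 0.10 in inhibitory neurons, within the range of random lists. Because this list pools Xist with Y-linked genes, its median does not show whether the libraries match in sex.

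**Figure D4:**
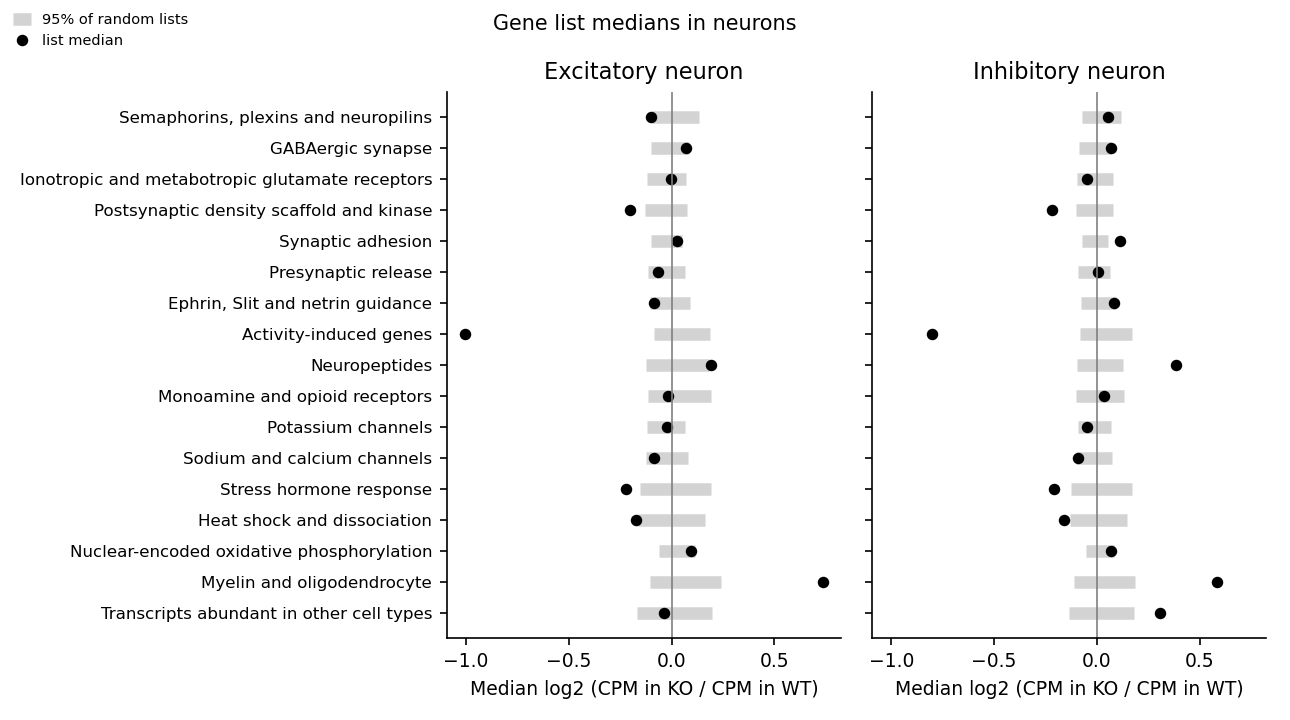
Median log2 ratio of CPM in the library labelled KO over CPM in the library labelled WT for gene lists in excitatory and inhibitory neurons (points), with the range that holds 95% of 10000 matched random lists (grey bars). Activity-induced genes lie lowest, at -1.01 and -0.80; the heat shock medians turn positive in thinned nuclei.

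The size rule then names single genes in neurons. Glo1 (ENSMUSG00000024026), the glyoxalase that detoxifies methylglyoxal, was the highest in both classes, at 9.48 CPM in WT and 28.7 CPM in KO in excitatory neurons (log2 ratio 1.60, 1.34 to 1.87) and 13.7 and 38.9 CPM in inhibitory neurons (1.51, 1.34 to 1.67). Btbd9 (ENSMUSG00000062202), a BTB domain protein, stood at 356 and 675 CPM in excitatory neurons (0.92) and 238 and 481 CPM in inhibitory neurons (1.01). Srm, the spermidine synthase, stood at 1.06 and 0.98, the zinc finger gene Zfp983 at 0.91 and 0.83, and Rsrp1 at 0.81 and 0.77. Also among the 10 highest in excitatory neurons were Pcdhb16, a protocadherin (0.99), the noncoding RNA Dancr (0.94), H3f3b, which encodes histone H3.3 (0.89), Scp2, a sterol carrier (0.84), and Ccbe1 (0.81). In inhibitory neurons these were Pla2g4e, a phospholipase (0.93), Slc17a6, a vesicular glutamate transporter that some nuclei of cluster 1 carry (0.78), Meox2 (0.76), Clcn6 (0.75) and Lrrc24 (0.74). Some of these differed alike in the other class, with H3f3b at 0.71 and Scp2 at 0.58 in inhibitory and Meox2 at 0.80 in excitatory neurons.

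Among the lowest genes, Crocc, which encodes the ciliary rootlet protein, stood at 32.5 CPM in WT and 15.4 CPM in KO in excitatory neurons (-1.07) and 46.7 and 19 CPM in inhibitory neurons (-1.30). Szrd1 stood at -1.06 and -0.98, and Zfp933 at -1.0 and -1.14. In excitatory neurons Cntnap5c, a contactin-associated protein, stood at 409 and 175 CPM (-1.22), Egr3 at -1.18, the GDNF receptor Gfra1 at -1.12, and Kcnip3, a calcium sensor that binds potassium channels, at -1.04. Ppp1r9b, which encodes spinophilin, stood at -1.0 and the repressor Bhlhe40 at -0.96. In inhibitory neurons the nuclear receptor Nr4a3 stood at 39.3 and 14.5 CPM (-1.44), the phosphatase Dusp14 at -1.19, Ivd, an enzyme of leucine breakdown, at -1.04, and Trmt6, a tRNA methyltransferase subunit, at -0.98. Traip stood at -0.95 and Miip at -0.87.

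The positions of some of these genes were examined. Btbd9, from 30215524 to 30576488, and Glo1, from 30584936 to 30626871, are neighbours on chromosome 17. Further genes up to Glp1r, a span whose ends were set after the values were seen, were higher in the KO library in neurons as well. Among them Dnah8, an axonemal dynein, had 12 UMIs in WT and 74 in KO (3.06), and Glp1r, the receptor of glucagon-like peptide 1, had 33 and 483 (4.30). Btbd9 was higher in all 8 groups compared, by 0.45 to 1.05, and Glo1 by 1.51 to 2.07. Ivd, Kcnip3 and Trmt6 lie on chromosome 2 at 118.9, 127.5 and 132.8 Mb, around Sema6d at 124.1 Mb. Rsrp1, Crocc, Szrd1, Zfp933, Miip and Srm lie on chromosome 4 between 134.9 and 148.6 Mb. Outside the span on chromosome 17 and the surroundings of Sema6d, genes that differed alike in both neuron classes had neighbours within 1 Mb about as often as random draws (16 against a median of 14). A count within 1 Mb cannot show whether longer stretches, such as that on chromosome 4, hold more such genes than random draws.

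**Figure D5:**
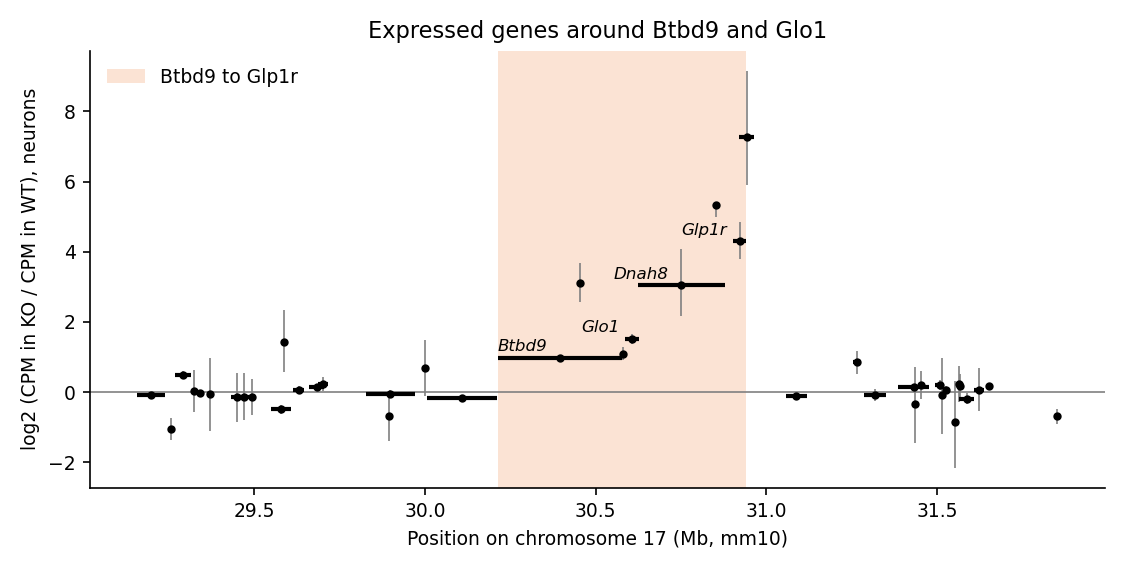
Log2 ratio of CPM in the library labelled KO over CPM in the library labelled WT in excitatory and inhibitory neurons together, against position on chromosome 17 (Mb, mm10), for genes with at least 20 UMIs in a neuron class. Horizontal bars span each gene, vertical lines are exact 95% intervals, and a gene with 0 UMIs in WT is drawn at the floor of 3 counts. The ends of the shaded span were set after the values were seen.

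In clusters 2 and 6 the lowest genes overlapped with those of other neurons. Cntnap5c stood at 293 CPM in WT and 49.1 CPM in KO in cluster 2 (-2.58) and at 104 and 4.09 CPM in cluster 6 (-4.67). Crocc stood at -2.00 and -2.63, Dusp14 at -1.53 and -1.90, Myo3b, a myosin, at -1.70 in cluster 2, and Slc26a10 at -2.22 in cluster 6. Higher in cluster 2 were Fv1, a retrovirus restriction gene (2.74), Glo1 (1.63), Atad2 (1.41) and Pla2g4e (1.36). In cluster 6 they were Glo1 (1.63), Pde9a, a cyclic GMP phosphodiesterase (1.45), Pla2g4e (1.40) and Dancr (1.21).

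In astrocytes, genes of cholesterol synthesis and uptake were higher in the KO library, with 17 of 18 members higher (median 0.62, percentile 100). Markers of another cell type were higher there too, with a median of 0.45 for myelin genes (15 of 19 higher, percentile 100). Msmo1, a sterol oxidase, stood at 181 CPM in WT and 274 CPM in KO (0.60) and Sqle, squalene epoxidase, at 30.3 and 59.7 CPM (0.98). Genes of astrocyte function were higher in 15 of 17 cases (median 0.47, percentile 100), and in oligodendrocytes in 14 of 17 (median 0.36), so this was not particular to astrocytes. In astrocytes they were led by Clu, a secreted chaperone, at 484 and 995 CPM (1.04, 0.94 to 1.15). The glutamate transporter Slc1a2 differed little, at -0.03, which turned to 0.06 with the same cluster weights. The list of reactive genes had a median of 0.08 over 6 members, with Gfap at 0.03 and Serpina3n, a protease inhibitor, at 3.24 from 6 and 43 UMIs. Stress hormone genes had a median of 0.02, with Fkbp5 at 1.21 and Pdk4, a brake on pyruvate oxidation, at -1.60. By the size rule Padi2, a peptidylarginine deiminase (2.26), Tshz3 (2.13), Agt, which encodes angiotensinogen (1.72), and Glo1 (1.52) were highest, and Ivd (-1.74), Pdk4, Coq10b (-1.50) and Rcan2, a calcineurin regulator (-1.42), were lowest.

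In oligodendrocytes, myelin genes were higher in the KO library in 17 of 19 cases (median 0.56, percentile 100). Mbp stood at 0.24 and Mobp at -0.12. The median of this list was also higher in both neuron classes, astrocytes and microglia, so the difference was not particular to oligodendrocytes. In oligodendrocytes other lists differed as well. Cholesterol genes had a median of 0.43, with 14 of 17 higher, and in precursors a median of 0.39, with 10 of 12 higher, within the range of random lists. Most neuronal lists were lower in oligodendrocytes, with medians of -0.74 for glutamate receptors, -0.69 for potassium channels (21 of 23 lower), -0.60 for sodium and calcium channels, -0.38 for ephrin, Slit and netrin guidance, -0.35 for the postsynaptic density and -0.24 for synaptic adhesion. The GABAergic synapse had a median of -0.08. How far neuronal RNA in these droplets sets such medians was not tested. By the size rule Glo1 (1.93), Olig2, a lineage transcription factor (1.86), the protease Klk6 (1.56) and Dus3l (1.44) were highest, and Fbrsl1 (-1.24), Cldn34c1 (-1.24), Snap23 (-1.12) and Sv2c (-1.04) lowest. In precursors Cd81, a tetraspanin (1.47), Tshz3 (1.46), Gpr37l1 (1.11) and Lrp1, a lipoprotein receptor (1.04), were highest, and the channel gene Kcnc2 (-1.34), Kcnip3 (-1.21), Ltbp1 (-0.93) and Neto2 (-0.92) lowest.

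In microglia, 12 of 12 homeostatic genes were higher in the KO library (median 0.38, percentile 99.8). The same list had medians of 0.41 in inhibitory neurons, 0.75 in oligodendrocytes and 0.68 in cluster 2, so the difference was not particular to microglia. In microglia, myelin genes had a median of 0.79, glutamate receptors -0.61 and sodium and calcium channels -0.61. Csf1r, the receptor for colony stimulating factor 1, stood at 0.53 and Olfml3 at 1.5. Genes of activated microglia had a median of 0.27, with Apoe at 0.50, and 3 interferon response genes had a median of -0.72, within the range of random lists. Mrc1 and F13a1, markers of border macrophages, stood at 10.9 CPM in WT and 273 CPM in KO and at 0 and 318 CPM, the latter 19.4-fold higher against a floor of 3 counts over the class. The lower end of the exact interval for F13a1 was a log2 ratio of 3.96. Of the microglia class 12 of 232 KO nuclei and 0 of 105 WT nuclei carried at least 2 border macrophage markers. Leaving out those nuclei, a choice made after seeing the data, lowers these ratios by construction (0.26 for Mrc1, and 0.81 for F13a1 against the same floor). Gatm, an enzyme of creatine synthesis, stood at 65.6 and 767 CPM (3.55, 2.72 to 4.52), and the lysosomal sulfatase Arsb at 1.55. A strain variant linked to Sema6d, raised below for genes of neurons, was not examined for genes named only in glia, Gatm included. Lowest were Arhgap31 (-1.17), the chromatin remodeller Arid1a (-0.98), Rapgef2 (-0.90) and the deubiquitinase Cyld (-0.88).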

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

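Every test of an explanation in this part was chosen after the shares had been seen. Of the nuclei and barcodes in no class compared, some were more and some less frequent in the library labelled KO. Called doublets were 4.25% in WT and 3.41% in KO, cluster 32, compared only by its share of neurons, was 0.910% and 0.471%, and cluster 30 was 0.919% and 1.06%. Cluster 17 carries both the oligodendrocyte gene St18 and the microglial gene Inpp5d and so has no name. It was 1.42% of nuclei in WT (1.2 to 1.67) and 2.18% in KO (1.87 to 2.52). Its medians were 10848 UMIs in WT and 10466 UMIs in KO, against 1891.5 and 1824 in oligodendrocytes and 1561 and 1548 in microglia. Excitatory neurons had medians of 9961.5 UMIs in WT and 10737 UMIs in KO. Whether the barcodes of cluster 17 are single nuclei was not tested. Cluster 19, with the neuronal genes Penk, Tac1 and Sst but medians of 1099 UMIs in WT and 855.5 UMIs in KO, was 1.09% and 2.39%. Barcodes with more than 5% mitochondrially encoded UMIs were 2.34% in WT and 4.94% in KO, while the median percentage in the analysed nuclei was lower in KO, at 0.751 in WT and 0.426 in KO, as it was in excitatory (0.570 and 0.187) and inhibitory neurons (0.711 and 0.318). Barcodes with fewer than 500 genes were 0.108% and 1.65%.

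The larger pattern is that oligodendrocyte, microglia and fibroblast nuclei were more frequent in the library labelled KO, a label that the Sema6d counts, not lower there, leave unchecked. A lower recovery of neurons would raise every other class alike, yet the share of astrocytes had a KO over WT ratio of 0.968 (0.875 to 1.07) while that of oligodendrocytes was 2.83 (2.55 to 3.15). The minimum of genes per nucleus is not the whole cause, since among nuclei with at least 1000 genes oligodendrocytes were still 4.16% in WT and 10.9% in KO. Different tissue taken at dissection stays open and may account for it. Of the 25 neuron clusters 6 also differed by more than 1.5-fold with an interval that leaves out 1. Among them is cluster 36, which carries Sim1 but scored highest for basolateral amygdala neurons. An effect of the genotype on these cell numbers stays open too, because each genotype has 1 library and neither was tested against the other.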

How the results depend on the processing

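Alternatives without clusters 1, 36, 17 and 19 and without border macrophage nuclei were chosen after seeing the data; all others were fixed before the data were examined. No paired analysis was possible because each group has 1 sample, and for the same reason leaving out a library was not possible. Some settings gave no value for a class, for instance where no cluster took its name. Of 67 recomputed differences in class share 60 stayed within the interval of the main value, as did 23 of 25 cluster ratios, 423 of 447 list medians (within the spread of random lists), 716 of 858 values of named genes and 6 of 8 Sema6d ratios. A further 133 values of named genes moved past their counting interval, which is narrow for abundant genes, without turning a direction whose interval left out 0. Scalings shifted all ratios of a class by less than 0.1. Depth limits what microglia and precursors show, since their classes hold 182893 to 672756 UMIs per library. The cause was not tested for any value below unless the setting itself shows it.

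With a minimum of 1000 genes the KO minus WT difference in share was 0.739 points for excitatory neurons, 6.73 for oligodendrocytes and 1.36 for microglia. This minimum removes many oligodendrocyte and microglia nuclei, whose median is 1113 to 1166 genes, and so enlarges the shares of neurons. The inhibitory difference was -9.24 with doublets kept, -8.86 at resolution 0.5 and -6.07 with WT clustered alone, where that of fibroblasts was 1.04. Excitatory nuclei per inhibitory nucleus moved with most settings, with or without the clusters kept out. At a minimum of 200 genes the ratio was 0.351 in WT and 0.322 in KO, at 1000 genes 0.531 and 0.608, with doublets kept 0.293 and 0.315, at resolution 0.5 0.260 and 0.278, at resolution 2.0 0.465 and 0.524, and with WT clustered alone 0.291 and 0.293. With the clusters kept out in the denominator it was 0.213 and 0.228 at 200 genes, 0.305 and 0.402 at 1000 genes, 0.202 and 0.225 at resolution 0.5 and 0.210 and 0.226 with WT clustered alone. In KO it was also 0.268 with doublets kept and 0.333 at resolution 2.0. With 50 components the cluster ratios were 0.827 for cluster 11 and 1.73 for cluster 13.

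In thinned nuclei the median of activity-induced genes was -0.80 in excitatory neurons and -0.89 in cluster 6, that of heat shock genes 0.0336 in excitatory and 0.0129 in inhibitory neurons, and that of myelin genes 0.16 and 0.77. Medians in thinned nuclei take only members that reach the minimum of UMIs after thinning, which can be fewer than in the main setting. Thinning also gave 0.52 for neuropeptides in cluster 2, 0.000346 for stress hormone genes in cluster 6, and 0.0679, 0.14 and 0.26 for the free RNA list in inhibitory neurons, astrocytes and precursors. The Sema6d ratio in thinned nuclei was 0.38 in excitatory neurons and -0.17 in cluster 2. With doublets kept, inhibitory medians were 0.18 for semaphorins, -0.63 for activity-induced genes and 0.50 for neuropeptides, and the free RNA list stood at 0.19 in precursors and 0.15 in microglia. With genes of at least 100 UMIs, medians were -0.38 for activity-induced and -0.26 for stress hormone genes in cluster 6 and 0.0794 for the free RNA list in inhibitory neurons. With genes of at least 1 UMI they were -0.25 for stress hormone genes in cluster 6 and 0.18 for the free RNA list in microglia. With the same cluster weights the median of ephrin, Slit and netrin guidance in inhibitory neurons was -0.0112. Without cluster 1 the heat shock median was 0.0703 and the free RNA median 0.11 in inhibitory neurons.

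Directions of 9 values of named genes turned, with main ratios between -0.19 and 0.26. With the same cluster weights the ratio was 0.17 for Nr4a2, -0.11 for Nxph1 and -0.0154 for Nr3c2 in excitatory neurons, -0.0315 for Nxph1 in inhibitory neurons, and 0.0565 for Slc1a2 in astrocytes. With median-of-ratios scaling it was -0.0031 for Dcc in inhibitory and -0.0233 for Dlg2 in excitatory neurons. With a minimum of 1000 genes it was 0.0232 for Sema6d and 0.0205 for Nrxn3 in inhibitory neurons.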

Other observations

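All tests of explanations in this part were chosen after the genes had been seen, and the genes named in these first paragraphs were chosen after their values were seen. The following single genes, which no list fixed in advance groups, were lower in the library labelled KO in both excitatory and inhibitory neurons. Dusp6, an ERK phosphatase, stood at -1.17 and -1.55 (log2 KO over WT), Dusp4 at -0.80 and -0.96, the feedback inhibitor Spry2 at -0.71 and -0.73, and the transcription factor Etv5 at -0.56 and -0.77. Irs2, an insulin receptor substrate, stood at -0.98 and -1.07. Gli3 and Ptch1, of the Hedgehog pathway, stood at -0.65 and -0.77 and at -0.67 and -0.60. In clusters 2 and 6, where Gli3 is a leading gene, it differed less, at -0.12 and -0.19, and in astrocytes it stood at -0.01. Ptch1 stood at -0.67 in cluster 2, -0.72 in cluster 6 and -0.02 in astrocytes.

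Astrocytes formed clusters that differed in opposite directions. Cluster 4, with Slco1c1 and Gli3 among its leading genes, was 7.67% of nuclei in WT (7.16 to 8.20) and 6.53% in KO (5.99 to 7.10), while cluster 21, with Etnppl and Itih3, was 1.14% (0.946 to 1.37) and 2.0% (1.70 to 2.33). Cluster 32, which carries Chat and Slc5a7 of cholinergic neurons, held 94 WT and 37 KO nuclei, a ratio of 0.642 within neurons (0.426 to 0.948). In cluster 2 the dopamine receptor Drd1 stood at 200 CPM in WT and 298 CPM in KO (log2 ratio 0.57, 0.48 to 0.67).

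Activity-induced genes such as Arc and Npas4 were lower in neurons of the library labelled KO. Another mix of neuron clusters is not the whole cause. With the same cluster weights in both libraries the list median was still -0.79 in the neuron class with the smaller difference and -0.97 in the other. Free RNA alone would lower the list in astrocytes as much, but there the median was -0.0693, against -0.80 in inhibitory neurons. Astrocytes may transcribe some members themselves, and single members there went both ways, with Homer1 lower and Nptx2 higher. A part played by free RNA is therefore not excluded. The median mitochondrial percentage of the same nuclei was lower too, at 0.570 in WT and 0.187 in KO in excitatory and 0.711 and 0.318 in inhibitory neurons. The state or handling of the animal before collection could lower such genes in every neuron class, and with 1 library per genotype it cannot be told apart from an effect of the genotype, which was not tested.

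Some genes differed alike in excitatory and inhibitory neurons, and their positions were examined. An extra copy of a chromosome segment on 17 would double its genes (log2 ratio 1). Of the 2 genes named there, the interval of Btbd9 (0.98, 0.95 to 1.02) holds that ratio, while that of Glo1 (1.52, 1.38 to 1.66) lies above it. In excitatory neurons alone the interval of Btbd9 (0.92, 0.88 to 0.97) lies below it. The other 6 genes of the span, most with few WT UMIs, were all higher, with a median of 3.70, above a doubling. Within 1 Mb on either side 16 of 34 genes were higher, with a median of -0.04. The span's ends were set after these values were seen. For these genes an extra copy cannot be told apart from other causes. As background, a duplication that spans Glo1 occurs in some inbred mouse strains and not in C57BL/6J. A strain variant linked to the targeted gene is a candidate explanation for others, since of the 100 genes that differed most alike 8 lie within 10 Mb of Sema6d on chromosome 2, among them Ivd, Kcnip3 and Slc24a5, against a median of 1 and an upper bound of 4 in random draws. Strain variants in blocks elsewhere in the genome stay undecided. Of the remaining genes 16 had a neighbour among them within 1 Mb, against a median of 14 and an upper bound of 23 in random draws. That distance is shorter than the 10 Mb used around Sema6d. It cannot show longer stretches, such as the one on chromosome 4 that holds Rsrp1, Crocc and Srm. Neither such blocks nor an effect of the genotype on these genes can be settled with 1 library each.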
